A study of Mus musculus with 6 samples.

How the data were processed

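Total RNA of SV40-immortalised, Cre-infected mouse embryonic fibroblasts, 3 wild type and 3 Rap1 knockout by the sample titles, was labelled with Cy3 and hybridised to Agilent mouse 4x44K arrays, per the labels' protocols. The deposited scanner files hold intensity values from Agilent Feature Extraction 10.5.1.1, per the file headers: a processed signal that the software had already corrected for background and detrended within each array, the median signal and local background of each spot, and flags for spots above background, saturated or outlying. The deposited value table holds log2 values of the same 6 arrays, and limma is named in the submitters' processing notes. Column by column, those log2 values correlated at 0.99999 with normexp-corrected (offset 50), quantile-normalised scanner signals, with column medians between 6.86 and 6.87. Which step of that processing the authors ran is not given in the sources used here. The knockout columns were matched to other scanner files than their labels name: columns 1, 2 and 3 held the values of scanner files 2, 3 and 1 of the same group. The groups are unaffected, but the replicate number and slide of a knockout array hold for the scanner files.

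Of 45018 spots, 1639 were control spots, which were left out, as were spots the software marked as outliers (74 to 120 per array). No spot was saturated. Spots of a probe were averaged, which gave 41174 probes. The main values were log2 of the processed signal minus the 75th percentile of each array. A probe was kept if well above background on all arrays of at least 1 group (25520 probes). Names came from RefSeq accessions in the files, matched without versions to a gene table of assembly GRCm38.p6: 23374 probes matched and 17800 kept the file's name. The files name mouse build mm8, so no coordinates were used and only the order of genes was taken from that table. A gene was represented by its kept probe of highest mean. The arrays lay on 2 slides, each scanned in 1 session: slide 1 held wild-type array 1 and knockout array 1, and slide 2 the other 4.

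Knockout was compared with wild type by limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 2-sided, Benjamini-Hochberg 0.05, no block). A probe not well above background on any array of a group has only a bound there: the mean of the brighter group was set against the dimmer group's mean of, per array, the higher of the lowest signal among probes well above background and the probe's own. Gene lists were tested by limma's camera (preset inter-gene correlation 0.01), with an estimated correlation and with fry beside it. Members were also adjusted over each list alone, with no adjustment across lists. Of 26 lists, 25 had at least 5 measured members and were tested; sex-linked genes had 4 and were not. For 10 of the 25 lists the median, the mean and the direction of the test did not share a sign: shelterin and telomerase, PPAR, NF-kB and p53 targets, Hox genes, patterning factors, TGF-beta, Wnt, endothelial and cartilage markers. The tests, the lists and the rule for named genes were fixed before the data were examined. The rule named Terf2ip and each shelterin or telomerase gene past the threshold, the 10 highest and 10 lowest fold changes among separated genes past it (skipping names that are only IDs, which skipped 1), and in each list the 3 members past it of largest fold change or, where none passed, the member of smallest p. Other genes named in the text were chosen after their values were seen.

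Distances of 5 Mb to chromosome ends and 10 Mb to Terf2ip had been planned. Gene order was used in their place, 40 protein-coding genes at each distal end and 80 on each side of Terf2ip, which was chosen after seeing the data, as were camera on the window around Terf2ip, the adjustment over the 7 position sets, and an estimated correlation and fry for them. The mean spot signal was not among the columns used, so normexp was run on the median signal. Alternatives were normexp, quantile and median scaling, the value table, no filter or a stricter filter on dim probes, the mean of a gene's probes, a trended robust variance, a 2-fold minimum, the replicate number or the slide as a block, and each array left out in turn. Averaging wild-type arrays 2 and 3, slide 2 alone and subtracting chromosome means were added after seeing the data. The median of all features lay at 0.07 (log2, knockout minus wild type), scaling by the array median moved it by 0.11, and dropping the filter on dim probes by −0.15. The list medians of shelterin, PPAR, p53 and TGF-beta turned below 0 after quantile normalisation, and that of cholesterol synthesis turned above 0 with median scaling.

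The tests were tried on simulated data: 20 runs of 3 against 3 arrays with 19657 features, 200 of them changed. The share recovered was 1.3% for a log2 change of 1, 54.1% for 2 and 94.2% for 4, and 6.7% of calls were false. A list of 30 genes shifted by 1 was found in 20 of 20 runs, and an unshifted one in 0 of 20 at an unadjusted p under 0.05. Genes and arrays were drawn independently of each other. The runs therefore do not bear on lists whose genes vary together, such as glycolysis and hypoxia (estimated correlation 0.57), or on arrays that are nearly alike. The Benjamini-Hochberg threshold is also stricter where fewer features change than the 200 set here, so the shares recovered need not carry over to the data. In the data, Epb41l4a at −5.66 (limma adjusted p = 0.1165) and Stmn2 at 4.26 (limma adjusted p = 0.1086) missed the threshold.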

Results

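RNA from mouse embryonic fibroblasts was measured on 6 one-colour (Cy3) Agilent mouse arrays, 3 labelled wild type and 3 labelled knockout for Rap1, the telomere protein encoded by Terf2ip that joins the shelterin complex through its partner Terf2. The fibroblasts had been immortalised with the large T antigen of the virus SV40 and infected with Cre recombinase, the enzyme that removes the floxed exon 3 of Terf2ip. Between 25393 and 27633 of 41174 probes per array (61.7% to 67.1%) were well above background, and 19657 features, 11877 of them with a gene symbol, entered the comparison. The number of arrays limits the precision. The labels do not say whether replicates came from separate embryos or cultures, so p-values measure only the spread between these samples.

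The comparison of knockout with wild-type cells addresses which transcripts depend on Rap1, near telomeres and elsewhere in the genome. Terf2ip itself checks the labels. Its 1 probe read −1.74 ± 0.08 (SD, n = 3; log2 signal relative to the array's 75th percentile) in wild type and was not well above background on any knockout array, where it read −8.36 ± 0.63. Terf2ip fell at least 37.7-fold (fitted log2 fold change −6.63, SE 0.34, limma adjusted p = 0.00803), on all 3 knockout arrays. Where this probe lies within the gene, inside or outside exon 3, was not determined here.

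The only other feature past the threshold was a transcript without a gene symbol, read by probe A_52_P381806, which was named because of its values and not by the rule for named genes. Its level fell from −0.20 ± 0.34 in wild type to −6.73 ± 0.67 in knockout cells (log2 fold change −6.53, SE 0.39, limma adjusted p = 0.0101), and 1 of 3 knockout arrays measured it above background. A second probe of the same transcript, A_52_P381813, read −0.53, −0.94 and −0.97 on the wild-type arrays and −8.62, −8.01 and −8.42 on the knockout arrays, where it was not well above background. After normexp correction with quantile normalisation the log2 fold change was −3.78 for the unnamed transcript and −2.62 for Terf2ip, and in the deposited value table −3.79 and −2.64. In all, 2 of 19657 features were lower in knockout cells and 0 were higher at a limma adjusted p under 0.05. An unadjusted p under 0.05, which chance alone gives for a share of 0.05, was reached by 2021 (1113 higher, 908 lower). With wild-type arrays 2 and 3 averaged it was reached by 688 (285 higher, 403 lower), a smaller share than chance gives. The groups did not overlap for 3402 features (17.3%, where chance gives 10% with 6 separate arrays and 20% with wild-type arrays 2 and 3 counted as 1), among them 330 at least 2-fold higher and 516 at least 2-fold lower in knockout cells. These 846 were fewer than the 893, 1054 and 1067 of the 3 other groupings of the arrays that keep wild-type arrays 2 and 3 together.

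Terf2ip differed by −6.16 on slide 1 and −6.86 on slide 2, and the unnamed transcript by −7.31 and −6.14. With the slide as a block, which cannot move a fold change here because each slide holds as many wild-type as knockout arrays, their limma adjusted p-values were 0.0635 and 0.0750 and 0 features passed (3489 at an unadjusted p under 0.05). Terf2ip missed the threshold without wild-type array 2 (limma adjusted p = 0.0766), wild-type array 3 (0.0592), knockout array 1 (0.0601) or knockout array 3 (0.0562), within a range of 0.00365 to 0.170 over its alternatives. The unnamed transcript missed it without wild-type array 2 (0.0766), wild-type array 3 (0.0592), knockout array 1 (0.0985) or knockout array 2 (0.0518), within 0.00147 to 0.170. In these 4 fits its log2 fold change was −6.59, −6.66, −6.33 and −6.34, and that of Terf2ip in its own 4 was −6.58, −6.66, −6.85 and −6.75. Wild-type arrays 2 and 3 were far closer to each other than any other pair (SD of the log2 difference 0.20, against 0.69 to 1.06). With these 2 averaged, limma called 0 features (688 at an unadjusted p under 0.05), without wild-type array 1 it called 64, and on slide 2 alone 303. In the fits with 64 and 303 calls, wild-type arrays 2 and 3 were the only wild type. The wild-type spread there was only that between these near-alike arrays, so these counts cannot be read as numbers of changed genes. Limma called 0 without wild-type array 2 (697 at an unadjusted p under 0.05), without wild-type array 3 (694), without knockout array 1 (1626) and over probes above background on all arrays (1784), a filter that removes Terf2ip and the unnamed transcript.

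**Figure D1:**
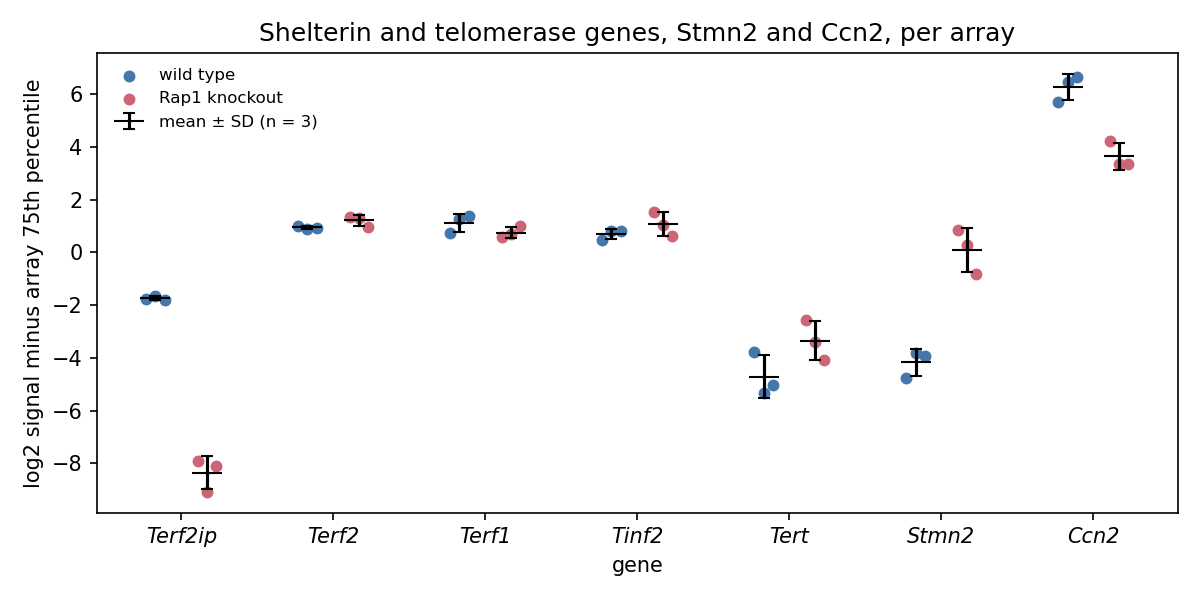
Normalised log2 signal (vertical axis, relative to the array's 75th percentile) of 7 genes in the 3 wild-type (blue) and 3 knockout (red) arrays, with bars at the mean ± SD. Terf2ip, the only gene plotted that passed the threshold, lies between −1.81 and −1.65 in wild type and between −9.08 and −7.91 in knockout cells, where it was not well above background.

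Of the 16 measured genes of shelterin and telomerase, 1 fell (Terf2ip), 0 rose and 15 did not pass, and adjusted over the list alone Terf2ip was again the only one. Terf2, which recruits Rap1 to telomeres, differed by 0.27 (SE 0.22) and Terf1, the other double-stranded telomere repeat binder, by −0.38 (SE 0.27). Tinf2, which bridges them, differed by 0.37 (SE 0.30), with 1.07 on slide 1 and 0.02 on slide 2. Tert, the catalytic subunit of telomerase, had a log2 difference of 1.37 (SE 0.54, limma adjusted p = 0.485) between a wild-type mean of −4.72 ± 0.83 and a knockout mean of −3.35 ± 0.75, and the groups overlapped. The list had a median of 0.10, a mean of −0.28 and a camera adjusted p of 0.903, so its median and its mean differed in sign. That mean includes the deleted gene Terf2ip itself at −6.63, while 9 members lay above 0 and 7 below, Terf2ip among the latter. The list's median was −0.01 after normexp correction with quantile normalisation.

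Among the 10 measured neighbours of Terf2ip on chromosome 8, 0 passed over all genes or adjusted over the list alone, and 0 had an unadjusted p under 0.05. Bcar1, an adaptor of focal adhesions, had the smallest p, with a log2 difference of 0.66 (SE 0.31, limma adjusted p = 0.496). The list's camera adjusted p was 0.692. In a wider window of 80 protein-coding genes on each side, in the gene order of assembly GRCm38.p6, 0 of 112 measured genes passed, against 0 of 11754 elsewhere with Terf2ip left out. At an unadjusted p under 0.05 the window held 9 genes (8.0%) against 1184 elsewhere (10.1%; Fisher's exact test, 2-sided, p = 0.634). The window's median log2 difference was 0.22, with 0.20 on slide 1, 0.26 on slide 2 and 0.06 with wild-type array 1 as the only wild type. Limma's camera, run on this window after seeing the data, gave an adjusted p of 0.0367 over the 7 position sets tested, 0.0460 for 40 genes on each side and 0.0452 for 160. None of the 3 windows held with an estimated correlation (adjusted p = 0.813 each) or with fry (adjusted p = 0.496 each).

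The genes at the distal chromosome ends, taken as the last 40 protein-coding genes of each chromosome, bore on subtelomeric silencing. Of 466 measured, 0 passed, against 1 of 11401 other genes, Terf2ip itself, which is too few calls to compare. At an unadjusted p under 0.05 there were 43 (9.2%) against 1151 (10.1%; Fisher's exact test, 2-sided, p = 0.583). Their median log2 difference was 0.04, with 0.14 on slide 1 and −0.02 on slide 2. Limma's camera gave an adjusted p of 0.666. The last 8 genes of each chromosome, 68 measured, had a median of −0.17 (limma camera adjusted p = 0.0367, adjusted p = 0.813 with an estimated correlation and 0.496 with fry). The last 16 had a median of −0.08 (limma camera adjusted p = 0.257) and the last 80 a median of 0.07 (limma camera adjusted p = 0.971).

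Of 25 gene lists tested, 2 passed with camera's preset correlation, cell cycle genes and genes of glycolysis and hypoxia. Neither held with an estimated correlation, where both had an adjusted p of 0.909, nor with fry, where the adjusted p was 0.389 for cell cycle and 0.882 for glycolysis and hypoxia. Neither list had a member past the threshold over all genes or adjusted over the list alone.

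Cell cycle genes lay higher in knockout cells as a list (camera adjusted p = 0.0253). Of 42 measured, 31 had a log2 difference above 0 and 11 below. All knockout arrays lay above all wild-type arrays for 14 and below them for 0. Over all features 17.3% were separated, both directions together, where chance gives 10%, or 20% with wild-type arrays 2 and 3 counted as 1. The members varied together (estimated correlation 0.10), so a chance share for independent genes does not apply to their count. None of the differences reached 2-fold. The median was 0.33, with 0.15 after quantile normalisation and 0.44 with median scaling. Cdc6, a loader of the replicative helicase, had the smallest p, with a log2 difference of 0.64 (SE 0.20, limma adjusted p = 0.469). Ccne1, the cyclin of entry into S phase, differed by 0.70 (SE 0.25) and Birc5, a mitotic passenger protein, by 0.65 (SE 0.25). The list's median was 0.31 on slide 1 and 0.24 on slide 2. The camera adjusted p was 0.0665 with the slide as a block, 0.348 after quantile normalisation, 0.173 without wild-type array 1 and 0.115 without knockout array 2, within a range of 0.00180 to 0.909 over its alternatives.

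Genes of glycolysis and the hypoxia response lay lower in knockout cells as a list (camera adjusted p = 0.0109). Of 29 measured, 22 had a log2 difference below 0 and 7 above, with a median of −0.31 and 8 at least 2-fold lower. Car9, a carbonic anhydrase, had the smallest p, with a log2 difference of −1.23 (SE 0.27, limma adjusted p = 0.325). The members ran from Egln3, a prolyl hydroxylase of the hypoxia-inducible factor, at −2.79 (SE 0.94) to Pfkm, a phosphofructokinase, at 0.61 (SE 0.22). Between them lay Bnip3, a mitophagy receptor, at −1.14 (SE 0.73), Hk2, a hexokinase, at −0.88 (SE 0.39), Ldha, a lactate dehydrogenase, at −0.14 (SE 0.36) and P4ha2, a collagen prolyl hydroxylase, at 0.03 (SE 0.43). The shift did not separate the groups array by array. Relative to each gene's mean over the 6 arrays, the list's median was −0.46, 0.41 and 0.50 on wild-type arrays 1, 2 and 3. On knockout arrays 1, 2 and 3 it was −0.38, 0.49 and −0.58. The list's median was −0.06 on slide 1 and −0.61 on slide 2, and 0.24 with wild-type array 1 as the only wild type. The camera adjusted p was 0.00677 with the slide as a block, 0.0946 without wild-type array 3, 0.0537 without knockout array 1 and 0.319 without knockout array 3, within a range of 1.43e-05 to 0.909 over its alternatives.

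**Figure D2:**
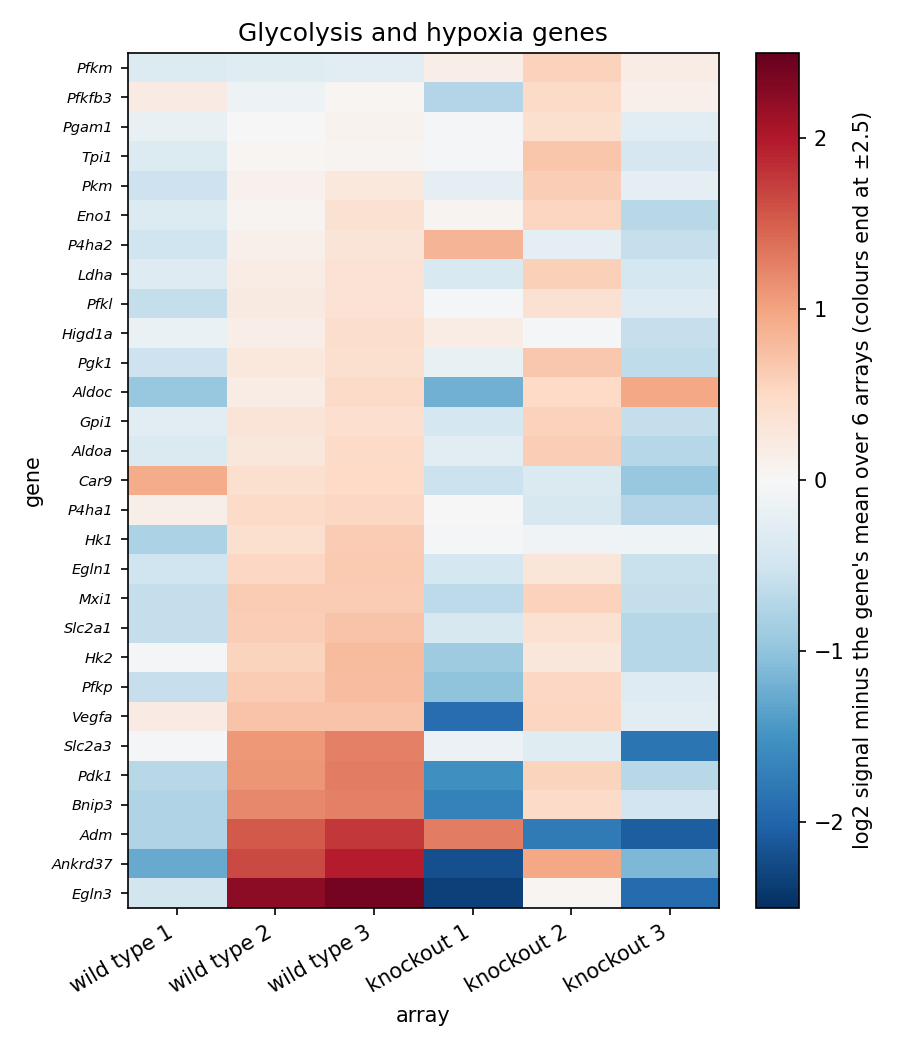
Log2 signal of the 29 measured glycolysis and hypoxia genes on each array, as colour, relative to the gene's mean over the 6 arrays. Wild-type arrays 2 and 3 lie above the gene means (list medians 0.41 and 0.50), wild-type array 1 below (−0.46), and knockout array 2 above (0.49).

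Adjustment over a list alone was not repeated for any list with wild-type arrays 2 and 3 averaged. In the other pathway lists, 0 members passed the threshold over all genes. ABC transporters had 0 of 25 past it and 3 higher adjusted over the list alone: Abcg1, a cholesterol exporter, at 2.85 (SE 0.45), Abcc4 at 1.15 (SE 0.26) and Abcb9 at 1.88 (SE 0.47); the list's camera adjusted p was 0.245. Among 36 genes of PPAR signalling none passed either way. Fabp4, a fatty acid carrier, had the smallest p with a log2 difference of −2.55 (SE 0.70, limma adjusted p = 0.428), and the list's camera adjusted p was 0.927. Of 39 cell adhesion genes, adjusted over the list alone, Mcam was higher at 1.65 (SE 0.25), and Alcam and Itga8 were lower at −2.67 (SE 0.52) and −3.27 (SE 0.69); camera gave an adjusted p of 0.692. The insulin-like growth factor and growth hormone axis (25 genes, 0 past the threshold adjusted over the list alone) had a camera adjusted p of 0.692, with Igf2 at −2.77 (SE 0.87), −4.83 on slide 1 and −1.75 on slide 2, and −1.69 without knockout array 1. Of 52 extracellular matrix genes, Col5a3 was higher adjusted over the list alone at 1.77 (SE 0.27), while 33 members had a difference below 0 and the list's median was −0.32 (camera adjusted p = 0.135, adjusted p = 0.909 with an estimated correlation). This list passed under 8 of 21 alternatives, within a range of 0.00474 to 0.909. The camera adjusted p was 0.00847 after quantile normalisation, 0.0278 with wild-type arrays 2 and 3 averaged, 0.0283 without wild-type array 2, 0.0201 without wild-type array 3 and 0.0126 without knockout array 1. It was 0.889 without wild-type array 1, 0.605 without knockout array 3 and 0.565 on slide 2 alone. Relative to each gene's mean over the 6 arrays, the list's median was 0.35, −0.03 and −0.01 on wild-type arrays 1, 2 and 3. On knockout arrays 1, 2 and 3 it was 0.17, 0.16 and −0.27, so the shift did not separate the groups.

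Targets of NF-kB (28 genes, 0 past the threshold adjusted over the list alone) had a list median of −1.23 on slide 1 and 0.83 on slide 2, 0.11 over all arrays (camera adjusted p = 0.903). Slide 1 held 1 array of each group, so the slide and single arrays cannot be told apart. On slide 2 alone the list passed (camera adjusted p = 0.00334), with the near-alike wild-type arrays 2 and 3 as the only wild type. Nfkb2, a subunit of the factor, differed by 0.89 (SE 0.28). Among 32 interferon-response genes, Ifi27l2a at −3.60 (SE 0.60) and Oas2 at −2.38 (SE 0.42) were lower adjusted over the list alone, and camera gave an adjusted p of 0.245, with 0.0361 without knockout array 3, within a range of 0.0361 to 0.947. The list's median was 0.42 on slide 1 and −0.41 on slide 2, −0.16 over all arrays and 0.04 with wild-type array 1 as the only wild type. Targets of p53 (29 genes, none past the threshold adjusted over the list alone, camera adjusted p = 0.692) had a median of 0.02, which was −0.06 after normexp correction with quantile normalisation, and Gadd45a differed by −1.03 (SE 0.36). The p53 values hold only for cells immortalised with the SV40 large T antigen, and cells without it were not measured. Among 33 genes of TGF-beta signalling and smooth muscle, Ccn2 at −2.64 (SE 0.37) and Fst, an activin inhibitor, at −2.15 (SE 0.31) were lower adjusted over the list alone, and the camera adjusted p was 0.692. Ccn2, a matricellular protein, differed by −1.50 on slide 1 and −3.20 on slide 2.

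**Figure D3:**
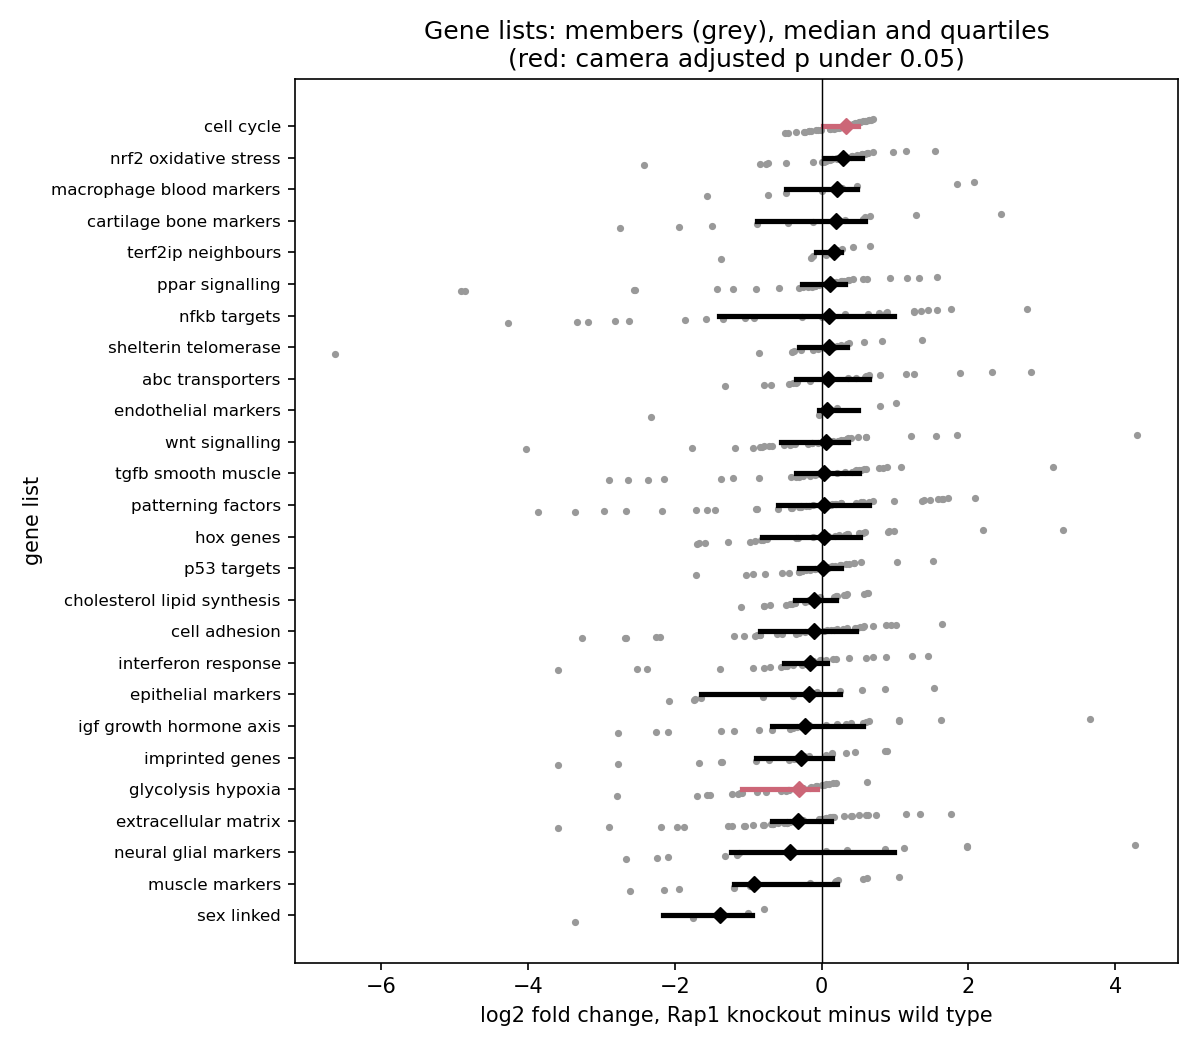
Log2 fold change, knockout minus wild type (horizontal axis), of the measured members of 26 gene lists (grey points), with each list's median (diamond) and quartiles (bar). The cell cycle list (median 0.33) and the glycolysis and hypoxia list (median −0.31), in red, had camera adjusted p-values of 0.0253 and 0.0109 with the preset correlation.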

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

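The alternatives of wild-type arrays 2 and 3 averaged, slide 2 alone, chromosome means subtracted and other gene numbers or set tests for the positions were chosen after the result was seen. Terf2ip lay lower in knockout cells under all 19 alternatives that could be run, between −6.86 and −2.62; the smallest shifts came from normexp, where an added offset compresses dim signals, and from the value table. Probes above background on all arrays exclude Terf2ip by construction. It missed the threshold at −6.63 under the slide block and at −6.62 with wild-type arrays 2 and 3 averaged, and without single arrays it ranged from −6.85 to −6.27. The adjusted p over its alternatives ran from 0.00365 to 0.170. Signal over background limits Terf2ip in knockout cells to a bound.

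By the numbers of the scanner files, the deviations of arrays of the same number correlated at 0.02, 0.05 and −0.07, which gave no sign of pairing. The order of the knockout arrays in the value table was not tried. With wild-type arrays 2 and 3 nearly alike, the values cannot tell their pairs apart, so a pairing of the samples stays open. With the replicate block 0 features passed (0 lower, 2354 at an unadjusted p under 0.05), Terf2ip missed the threshold at −6.63, a value this block cannot move, and 1 list passed. The slide block gave 0 features, 0 lower, and 1 list. The averaged wild-type arrays and the stricter filter each gave 0 features and 0 lower. The mean of a gene's probes gave 4 features, 1 higher. Subtracting chromosome means, over 11878 features with a known chromosome and so without the unnamed transcript, gave 1 feature, 1 lower, and 5 lists. Slide 2 alone, where the near-alike wild-type arrays 2 and 3 were the only wild type, gave 303 features. Of these 175 were higher and 128 lower. They held 12 of 466 distal genes and 3 of 112 near Terf2ip, beside 303 of all 19657 features. Without single arrays the counts ran from 0 to 64 features, 0 to 29 higher, 0 to 35 lower, 0 to 4 distal genes and 1 to 3 lists. The most features came without wild-type array 1, which also leaves only that near-alike pair as wild type. With no filter 4 lists passed, with an estimated correlation 0 and with fry 0. The higher share of features at an unadjusted p under 0.05 was 55.1%, 65.4% with median scaling, 44.6% with no filter, 47.8% with the replicate block, 41.4% with wild-type arrays 2 and 3 averaged, 39.9% without wild-type array 2 and 42.7% without wild-type array 3. Of the lists not past the threshold, extracellular matrix passed under 8 alternatives, cholesterol synthesis under 5, epithelial markers under 2, and NF-kB, interferon and NRF2 under 1 each; sex-linked genes, with enough measured members only with no filter, passed there. The 2-fold minimum does not bear on lists. For other changes of count, the cause was not tested.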

Other observations

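Tests on the likeness of wild-type arrays 2 and 3, on chance as a source of chromosome shifts and on Eif2s3y were chosen after the result was seen. Lists of cell types and developmental genes had 0 members past the threshold over all genes, and none passed as a list. Neural and glial markers (15 genes, camera adjusted p = 0.692) held Stmn2, a microtubule regulator of neurons, at a log2 difference of 4.26 (SE 0.48, limma adjusted p = 0.109), on both slides (5.60 and 3.60), and S100b at −1.32 (SE 0.31), both past the threshold adjusted over the list alone. Muscle markers (15 genes, camera adjusted p = 0.245) held Tnnt3, a troponin, at −2.61 (SE 0.40, measured above background on 2 of 3 knockout arrays), and cartilage and bone markers (13 genes, camera adjusted p = 0.692) held Mgp at −1.49 (SE 0.32) and Comp at 2.45 (SE 0.62), all 3 past it adjusted over the list alone. Epithelial markers (13 genes, camera adjusted p = 0.245) held Trp63 at −1.64 (SE 0.30) and macrophage and blood markers (9 genes, camera adjusted p = 0.967) held Coro1a at 1.84 (SE 0.36), each past it adjusted over the list alone. Endothelial markers (7 genes, camera adjusted p = 0.967) had none past it, with Flt1 at −2.33 (SE 0.76).

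No member passed the threshold, over all genes or adjusted over the list alone, in the following lists. These were Hox genes (28 genes, camera adjusted p = 0.692), other patterning factors (41 genes, camera adjusted p = 0.692) and Wnt signalling (36 genes, camera adjusted p = 0.692). They also included imprinted genes (21 genes, camera adjusted p = 0.245), the NRF2 oxidative stress response (32 genes, camera adjusted p = 0.245) and cholesterol and lipid synthesis (30 genes, camera adjusted p = 0.249). Among the patterning factors, En1 was at least 3-fold lower by the group means (limma adjusted p = 0.319), since it was not well above background on any knockout array. Its log2 difference was −1.03 on slide 1 and −3.94 on slide 2. Fzd3, of the Wnt list, differed by 1.85 (SE 0.76) and was measured above background on 2 of 3 wild-type arrays. Igf2 again had the smallest p of the imprinted genes. Of the NRF2 genes, 26 lay above 0 (median 0.29), and Abcc4 had the smallest p. Msmo1, of the cholesterol list, differed by −0.78 (SE 0.29). Sex-linked genes (4 measured) had 1 lower adjusted over the list alone, Ddx3y at −1.76 (SE 0.48), with −0.48 on slide 1 and −2.40 on slide 2. The list's median was −1.38, and −0.26 with wild-type array 1 as the only wild type. The next features by p, all with a limma adjusted p of 0.109, included Cyfip2 at 2.94, Crmp1 at 2.48, Sec14l2 at 1.96 and Serping1 at −2.01.

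Of the 10 splits of the 6 arrays into 3 and 3, the real one called 2 features and the highest other 16, and 2 splits called at least 2. For lists the real split had 2 and the highest other 6, and 9 splits had at least 2. The 10 splits are too few for a share under 0.05. The split that called 16 set wild-type array 1 with knockout arrays 2 and 3. The 4 splits that keep wild-type arrays 2 and 3 together had 2021 (the real one), 2968, 2424 and 1607 features at an unadjusted p under 0.05. The other 6 had between 142 and 315. These counts went with whether the near-alike pair was kept together, and the real split was not the highest.

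Wild-type arrays 2 and 3 were nearly alike: the SD of their log2 difference over probes above background on all arrays was 0.20, against 0.69 to 1.06 for the other 14 pairs. They differed by 4.01 times the error that replicate spots allow, which argues against 1 hybridisation deposited in duplicate. The deviations of single spots at the same positions correlated at 0.488 (95% bootstrap interval 0.396 to 0.562), which by itself left a duplicate open. In other pairs these deviations correlated at 0.146 to 0.442, the highest for wild-type array 1 and knockout array 3, which lay on different slides. The shared slide does not account for the likeness, since knockout arrays 2 and 3 on slide 2 differed 3.95 times as much. RNA or cells of 1 origin on both arrays stays open as a candidate explanation. Their largest difference, on Y genes and on chromosome means, was at most 0.0339 of that among the other 4 arrays. Arrays already seen to be alike over all probes would be close on these measures too, so this cannot decide the origin. The labels name no biological difference between these 2 arrays, and none was tested apart from the origin.

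Whole chromosomes lay apart in single arrays, such as chromosome 7 (mean −0.42) and X (−0.47) in knockout array 1 and chromosome 12 (−0.35) in knockout array 3. Chance does not account for it, with a variance of the chromosome means 4.49 times the highest of 1000 shuffles of genes. The Spearman correlation of the means with the number of genes was 0.0053 in size in knockout array 3, which argues against gene number as the cause there, and between −0.33 and 0.20 in the other arrays, where a part played by it stays open. Differences in copy number between the cells may account for it: the first and second part of each chromosome correlated at 0.693, against at most 0.478 in 1000 re-pairings. No DNA was measured, and a difference between embryos stays open, as untested.

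Eif2s3y, a gene of the Y chromosome, read −5.53 in knockout array 1 and between −0.62 and 2.03 in the others. Loss of the Y chromosome is argued against by Ddx3y, Kdm5d and Uty, whose median difference between that array and the others was −0.0091, against −6.31 for Eif2s3y. What lowered Eif2s3y there stays open.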
